A study of Arabidopsis thaliana with 6 samples.

How the data were processed

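Leaves of Arabidopsis thaliana plants aged 3 to 4 weeks were sprayed either with 0.01% Silwet, a wetting agent, or with 1 mM salicylic acid (SA) in 0.01% Silwet, and were harvested 2 hours later. Per the labels, 3 biological replicates of each treatment were collected, and each was hybridised to 1 Affymetrix ATH1 array, which makes 6 arrays. The labels describe a phenol and chloroform extraction of total RNA from frozen leaves and biotinylated cRNA as the target.

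The deposited table holds 22810 probe sets as log2 signals, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, applies quantile normalization between arrays and summarises the probes of each probe set on the log2 scale. The version of RMA and any filter are not given in the sources used here. Scanner files were not used here. The median log2 signal per array lay between 7.41 in SA replicate 1 and 7.51 in mock replicate 3, and the interquartile range between 3.33 and 3.53. Pearson correlations between arrays over all probe sets without controls ran from 0.959 to 0.986, and no pair of arrays held the same values throughout. The number of arrays limits the precision of every value, and an exact test of 3 arrays against 3 cannot give a two-sided p below 0.1. Quantile normalization brings the arrays towards 1 distribution, so a shift shared by most transcripts would be largely removed from these values. The deposited values are not on exactly 1 distribution. Their medians followed treatment, at 7.41 to 7.46 in the 3 SA arrays and 7.49 to 7.51 in the 3 mock arrays.

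A total of 64 AFFX control probe sets were kept out of all tests, which left 22746 probe sets. The annotation given with the platform listed 14016 of these, of which 13513 had 1 gene and 503 had several. The other 8730 were not listed and are unnamed here. Of the probe sets with 1 gene, 13436 were matched through the gene identifier to a locus of the RefSeq annotation of assembly TAIR10.1, which supplied gene symbols and the order of neighbouring genes. For 144 loci with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept; at 2 of these loci the probe sets differed in whether they passed the test, and at 0 of them in direction. This gave 13286 genes. For 11751 of them the RefSeq symbol is the locus name itself, and they are named by locus.

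Before the data were examined, the tests, the alternatives, 30 gene lists with 518 members and the rule for naming genes were fixed. Only 82 list members were measured under a matched locus, in 24 lists. The genes named are the 10 largest rises and the 10 largest falls among genes past the test whose groups did not overlap, 10 SA and jasmonate marker genes whatever their values, and up to 4 members of each list with the smallest p. Of those 10 marker genes, 2 were measured under a matched locus, GRX480 and PDF1.2; PR1, PR2, PR5, NPR1, NIMIN1, WRKY70, ICS1 and UGT74F2 were not analysed here. Lists with at least 3 measured members were tested, 16 in all; that limit was set after the data were examined.

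Differences between SA and mock were fitted on the log2 values as deposited with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with treatment group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and 2-fold refers to an absolute log2 change of at least 1. All adjusted p-values of genes are from this moderated test. Values with ± are the log2 change and its standard error from the fit. Gene lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 16 lists, and again with an estimated correlation. The fry test, which asks whether the genes of a list move on balance one way, was run beside it. Members were also counted after adjustment over the list alone.

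The 2 treatments share replicate numbers. The deviations of the arrays from their group means correlated across probe sets by 0.75, 0.46 and 0.55 for the arrays numbered 1, 2 and 3, all above the limit of 0.1 set for this check, so the numbers were taken to pair the arrays. Of the pairs with different numbers, mock 3 with SA 2 was above that limit as well, at 0.14, and the others were below 0. This pairing comes from the values; the labels do not say what a number marks. The fit with the replicate number as a block is therefore given beside results that it changes. The median residual SD per gene was 0.177 without the block and 0.115 with it, while the residual degrees of freedom fell from 4 to 2.

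The scripts were tested on simulated data for the SA and mock comparison of 13286 genes, with pair effects and spreads taken from the real arrays and 200 changed genes in each of 5 runs. Without the block, 77.2% of genes changed by 1 log2 unit and 97.0% of genes changed by 2 were recovered, and 0.110% of calls were false. With the block, 99.2% and 99.8% were recovered, and 8.16% of calls were false, which is above the nominal 5%. A planted list of 8 genes raised by 1 log2 unit passed camera in 5 of 5 runs in both fits, and 0 of 55 unchanged lists did. Simulated genes were drawn independently of each other, so these runs do not show how often unchanged lists of correlated genes pass. The estimated correlation in the real detoxification list was 0.43.

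Alternatives covered the replicate block, cyclic loess or median centring on top of RMA, leaving out the dimmest 33.3% of probe sets, adding 32 linear units before the log, a trended robust prior, array weights, another choice of probe set per gene, leaving out probe sets shared between genes, testing against a log2 change of 1, and leaving out each array in turn. Leaving out both arrays numbered 1, a block that sets replicate 1 apart, and the block together with an estimated correlation were added after seeing the data.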

Results

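The series measured transcript levels in Arabidopsis thaliana leaves 2 hours after plants were sprayed with salicylic acid, a phenolic hormone of plant defence. The SA group received 1 mM SA with the wetting agent Silwet at 0.01%, and the mock group received Silwet alone. Each group comprised 3 biological replicates on 1 array each, and 13286 genes were measured by 1 probe set each. The comparison addresses which leaf transcripts differ between SA-treated and mock-treated plants at this time.

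UGT76B1 (AT3G11340), a glucosyltransferase that acts on SA and on isoleucic acid, showed the largest rise. Its log2 signal was 6.21 ± 0.71 (SD, n = 3) in mock leaves and 12.64 ± 0.25 (SD, n = 3) in SA-treated leaves, an 86.2-fold difference (limma adjusted p = 0.00625). GRX480 (AT1G28480), a CC-type glutaredoxin that interacts with TGA transcription factors, rose 10.8-fold, by 3.43 ± 0.26 log2 units (adjusted p = 0.0115). XERICO (AT2G04240), a RING-H2 protein linked to abscisic acid homeostasis, fell by 1.75 on the log2 scale, with a standard error of 0.22 (adjusted p = 0.0300).

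The other 8 of the 10 largest rises among called genes with a matched locus were carried by genes without a symbol in the annotation. Probe sets unnamed here, some with larger changes, are given further below. AT4G22530 rose by 3.28 ± 0.26 log2 units, AT5G51830 by 2.99 ± 0.27, AT1G08050 by 2.90 ± 0.31 and AT5G03350, which encodes a legume-type lectin domain protein, by 2.80 ± 0.25. The mean log2 signal of AT5G03350 was 11.03 in mock and 13.83 in SA-treated leaves. AT3G57700, AT5G52810, AT5G46230 and AT4G22980 rose by 2.74, 2.60, 2.50 and 2.49 log2 units. Adjusted p-values of these 8 genes lay between 0.0114 for AT4G22980 and 0.0324 for AT5G52810.

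The falls were smaller. Among called genes with a matched locus, AT3G15570 showed the largest. Its mean log2 signal was 9.38 in mock and 7.26 in SA-treated leaves, a change of -2.12 ± 0.19 (adjusted p = 0.0141). AT1G78450 and AT5G03230 fell, with log2 changes of -1.83 and -1.78. AT5G45650, a subtilisin-like protease gene, fell by 1.49, and AT1G20823, which encodes a RING-type zinc finger protein, fell by 1.63. AT3G56080, AT1G74940, AT1G78995 and AT5G23920 fell, with changes of -1.66, -1.64, -1.49 and -1.44. Adjusted p-values of the 10 falls reached 0.0467, close to the threshold, in AT3G56080 and AT5G23920.

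**Figure D1:**
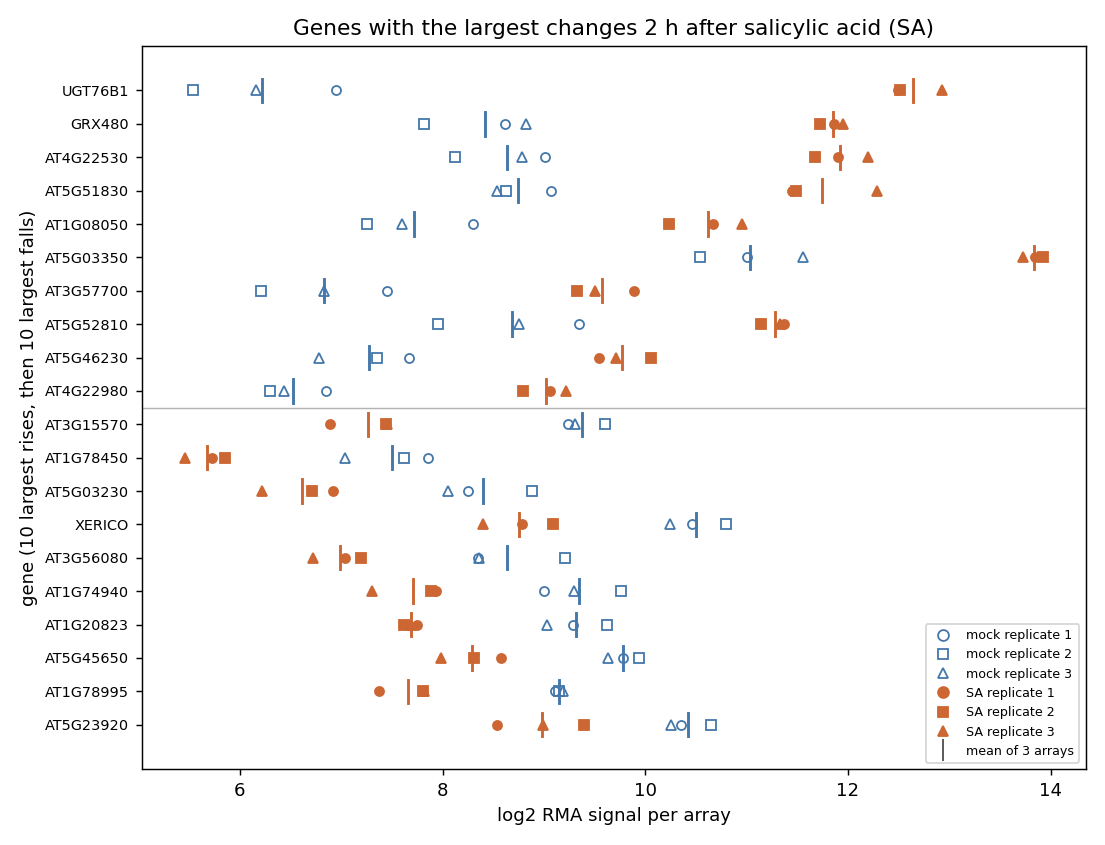
Log2 RMA signal (horizontal axis) of each array for the 10 genes with the largest rises (upper part) and the 10 with the largest falls (lower part); open symbols are mock arrays, filled symbols SA arrays, shapes give the replicate number and vertical bars the mean of 3 arrays. By the rule for naming genes the 3 SA arrays lie apart from the 3 mock arrays in every gene drawn, with UGT76B1 at means of 6.21 and 12.64.

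Across all genes, limma called 217 at an adjusted p under 0.05, of which 138 rose and 79 fell (63.6% rises). Rises ranged from 0.51 to 6.43 log2 units with a median of 1.21, and falls from -0.56 to -2.12 with a median of -0.87. At least 2-fold changes numbered 113, with 85 rises and 28 falls. This count joins the test against no change with the fitted size. Tested against a log2 change of 1 over all 6 arrays, only UGT76B1 passed. By the joint rule of adjusted p and fitted size, fits without 1 array gave 5 to 55 genes changed at least 2-fold. All 217 genes had groups that did not overlap, a separation that chance gives to 10% of unselected genes with 3 arrays against 3. These genes were selected by a small p from the same values, so their separation is no independent support. The unadjusted p was under 0.05 in 1836 genes. Uniform p-values would give 664.3, and the split of mock 1, mock 2 and SA 1 against the other arrays gave 1928. The other splits that part all 3 pairs gave 68 to 150. Those splits keep the difference between SA and mock inside their groups, so their counts are no measure of what chance gives. The median change over all genes was -0.0077 log2 units.

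With the replicate number as a block, 1316 genes were called, 684 rises and 632 falls (52.0% rises), and 342 changed at least 2-fold; all 217 genes were among them. The probe set AFFX-DapX-3_at of the dap spike-in control gave log2 signals of 11.52 and 11.42 in mock and SA replicate 1 and between 8.27 and 8.44 in the other 4 arrays, so it separated the arrays numbered 1 from the rest in both treatments. A block for that split called 684 genes, and the 4 arrays numbered 2 and 3 alone gave 4, UGT76B1, AT3G28510, AT4G13180 and AT3G62550, a set named after its values were seen. Fits without mock replicate 1, 2 or 3 called 57, 5 or 15 genes, of which 46, 5 and 15 were among the 217. Fits without SA replicate 1, 2 or 3 called 22, 6 or 24, of which 18, 4 and 24 were among them. Of the 20 genes with the largest changes, 11, 3 and 5 passed without mock replicates 1, 2 and 3, and 8, 1 and 6 without SA replicates 1, 2 and 3. Centring the arrays on their medians changed the split to 157 rises and 56 falls, 73.7% rises.

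Over the 22746 probe sets, without any gene annotation, limma called 334, with 222 rises and 112 falls, and 2365 with the replicate block. Probe sets unnamed here supplied 103 of these rises and 45 of these falls. The largest were 249890_at, with a rise of 5.92 ± 0.49 log2 units from a mock mean of 4.91, and 260904_at, with a rise of 5.15 ± 0.33 from a mock mean of 7.26. Among unnamed falls, 258497_at changed by -2.15 ± 0.22 and 254835_s_at by -2.15 ± 0.33. Counts without annotation also moved when arrays were left out, to 98, 2 and 0 probe sets without mock replicates 1, 2 and 3 and to 36, 0 and 0 without SA replicates 1, 2 and 3.

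Genes of SA perception and metabolism were represented by few measured members. In the list of NPR1 and its partners, 1 of 16 members was measured, GRX480, and it rose. Of the 5 measured genes of SA modification, UGT76B1 rose, and the other 4 did not pass the test, with log2 changes of 0.13 in UGT74F1, 0.14 in WES1, -0.42 in UGT71C3 and -0.83 in BSMT1, a methyltransferase. UGT74F1 is a glucosyltransferase that also acts on SA. The list did not pass camera (adjusted p = 0.551), and its median of 0.13 lay well below its mean of 1.09, which UGT76B1 raised. By fry its p for a shift on balance was 0.00435 (adjusted 0.0696), and its adjusted p for change in either direction was 0.000401. SAG101, the only measured gene of the SA synthesis list and a partner of EDS1 in immune signalling, had a change of 0.52 ± 0.50 (adjusted p = 0.796).

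WRKY53, the only measured WRKY factor among those listed as NPR1 targets, had a mean log2 signal of 9.46 in mock and 10.90 in SA-treated leaves, a change of 1.45 ± 0.42. It did not pass without the block (adjusted p = 0.185) and passed with it (adjusted p = 0.0232). Among 6 other WRKY factors the median change was 0.13, and limma called 0 of them without the block, with 1 at an unadjusted p under 0.05, and WRKY6 with it (log2 change 0.67, adjusted p = 0.0290 with the block and 0.360 without). WRKY20, WRKY22 and WRKY42 had changes of 0.23, 0.18 and 0.088.

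The detoxification list was the only 1 of 16 tested lists that passed camera (adjusted p = 0.0118, direction up; adjusted p = 0.0227 with the replicate block). With an estimated correlation its p was 0.140 and its adjusted p = 0.882, so the call was lost. The median change of its 7 measured members was 1.01 log2 units, and 6 of the 7 lay above 0. The 3 glycosyltransferases UGT73B5, UGT73B4 and UGT73B1 had changes of 1.78 ± 0.40, 1.53 ± 0.51 and 1.53 ± 0.52, and AER, an alkenal reductase, 1.01 ± 0.35. No member passed the test over all genes, where 6 had an unadjusted p under 0.05; 4 rises passed when adjusted over the list alone. With the block 6 rises and 1 fall, of AT2G04050, passed over the list alone, and UGT73B1 passed over all genes (limma adjusted p = 0.0217). By fry the p of the list was 0.0635 (adjusted 0.508) for a shift on balance, and its adjusted p for change in either direction was 0.207. The list medians in the pairs numbered 1, 2 and 3 were 0.66, 0.68 and 1.90. The adjusted p rose to 0.0723 without mock replicate 1, to 0.101 without mock replicate 3 and to 0.0809 with array weights.

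**Figure D2:**
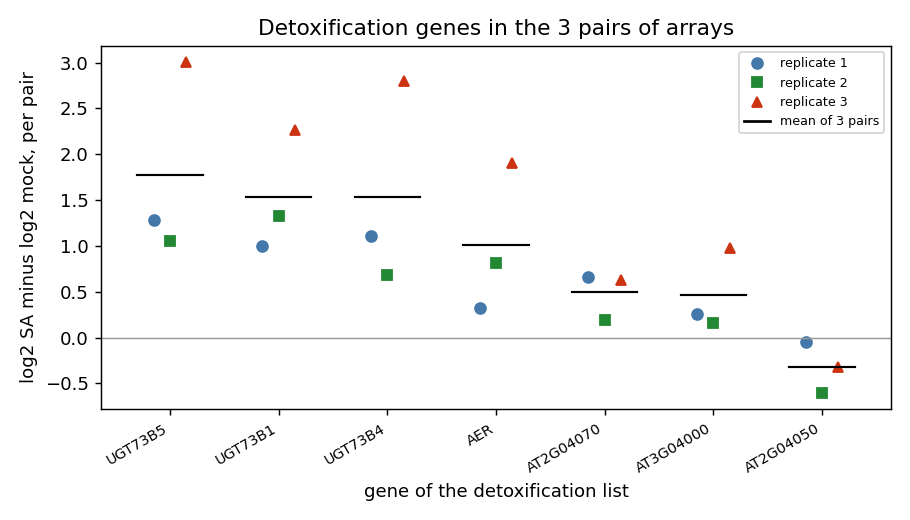
Log2 difference between the SA and the mock array of the same replicate number (vertical axis) for the 7 measured genes of the detoxification list (horizontal axis); symbols give the replicate number and horizontal bars the mean of 3 pairs. Pair 3 lies highest in 5 of the 7 genes, with list medians of 0.66, 0.68 and 1.90 in pairs 1, 2 and 3.

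The fixed list of glutathione S-transferases had 8 measured members, all of the tau class, of which limma called 0 without the block, with 2 at an unadjusted p under 0.05. With the block GSTU18 fell by 0.92 on the log2 scale (adjusted p = 0.00588, against 0.105 without) and GSTU27 rose by 0.66 (adjusted p = 0.0146, against 0.339 without). The list median was 0.13 and its camera adjusted p = 0.870. Adjusted over the list alone and without the block, the fall of GSTU18 passed.

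In the mitochondrial dysfunction list, NDB2, an alternative NADH dehydrogenase, rose by 1.27 ± 0.19 log2 units (adjusted p = 0.0445). This call was lost with 32 linear units added (adjusted p = 0.0598) and without any 1 of the 6 arrays, where the adjusted p of NDB2 ran from 0.0690 to 0.180. The other 2 measured members had negative changes, AT2G21640 with -0.75 (adjusted p = 0.193, and 0.0273 with the block) and AT5G51440 with -0.47. The median of -0.47, the mean of 0.018 and the camera direction, which was up without the block and down with it, differed in sign (adjusted p = 1.000). GR1, a glutathione reductase and the only measured member of the antioxidant list, had a change of 0.19 (adjusted p = 0.754).

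PUB24, a U-box ubiquitin ligase that dampens pattern-triggered immunity, rose 2.83-fold, with a standard error of 0.25 on the log2 scale (adjusted p = 0.0493). The call of PUB24 was lost with 32 linear units added (adjusted p = 0.0755) and without any 1 of the 6 arrays (adjusted p from 0.0680 to 0.209). BIK1, a receptor-like cytoplasmic kinase of the same list, had a change of 0.54 (adjusted p = 0.273), and PUB22 and PUB23, close relatives of PUB24, had changes of 0.032 and 0.085. The list had a median of 0.31 and a camera adjusted p of 0.170, and 0.000583 when SA replicate 2 was left out. The touch and wounding list had an adjusted p of 0.253 over all arrays and 0.000849 without SA replicate 2. Those values use the preset correlation; with an estimated correlation over all arrays both lists had an adjusted p = 0.882. Its members CML37, CML38 and STZ had changes of 1.32, 0.48 and 0.30, of which limma called 0 without the block, with 1 at an unadjusted p under 0.05, and CML38 with it (adjusted p = 0.0334).

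Among other hormone pathways, PDF1.2, a plant defensin induced by jasmonate and ethylene, had a change of -1.06 ± 0.60, within the spread between replicates (adjusted p = 0.541). Its differences in the pairs numbered 1, 2 and 3 were -0.30, -0.42 and -2.45. PDF1.2b, THI2.1 and JMT had changes of -0.87, -0.55 and 0.28, and the list of 4 jasmonate genes did not pass (adjusted p = 0.671), with pair medians of -0.21, 0.13 and -1.89. GH3.3, an enzyme that conjugates auxin to amino acids, changed by 1.94 ± 0.52; its adjusted p was 0.162 without the block and 0.00364 with it. IAA29 and GH3.1 had changes of -1.11 and 0.011, and the auxin list did not pass (adjusted p = 0.817). The abscisic acid and dehydration genes COR15B, COR47 and COR15A had changes of -0.76, -0.54 and -0.43, with a list adjusted p of 0.533. EIN3, the only measured member of the ethylene list, had a change of -0.18.

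Photosynthesis transcripts gave small differences. The 8 measured genes had a median change of -0.091, the largest being -0.25 ± 0.11 in PRK and -0.23 ± 0.10 in LHCB4.2, and limma called 0 of them in either fit, with 0 at an unadjusted p under 0.05 without the block. Of these 8 genes, 7 lay below 0, and the list did not pass camera (adjusted p = 0.253). In the cell wall list EXPA8, an expansin, had a change of -1.32 ± 0.38 that passed over all genes only with the block (adjusted p = 0.00923, against 0.186 without) and over the list alone without it as well. XTH33 and EXPA4 had changes of 0.32 and -0.16 (list adjusted p = 0.817). The phenylpropanoid and flavonoid genes UGT78D1, DFR and UGT78D2 had changes of -0.96, -0.39 and -0.17 (list adjusted p = 0.551). GI, the only measured member of the clock list, had a change of -0.54 (adjusted p = 0.404).

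Endoplasmic reticulum and secretory genes had a median change of -0.086 over 4 members, CRT1b, AT5G07340, BZIP60 and ATERDJ3B (camera adjusted p = 0.817), with 0 at an unadjusted p under 0.05 in limma. The 5 heat shock genes had a median near 0 (adjusted p = 1.000), with the highest change, 0.57 ± 0.61, in AT1G53540. Markers of other leaf cell types did not pass the test either, with -0.22 ± 0.13 for FMA of guard cells and -0.36 ± 0.31 for TRY of trichomes. The 5 reference genes had a median of -0.059 (adjusted p = 0.870), and the changes of GAPC2, AT2G28390, AT4G34270 and AT5G46630 were -0.059, -0.13, -0.069 and 0.18. For pathogenesis-related genes, receptor kinases, NLR receptors, indole metabolism, senescence and floral markers, no listed member was analysed here.

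**Figure D3:**
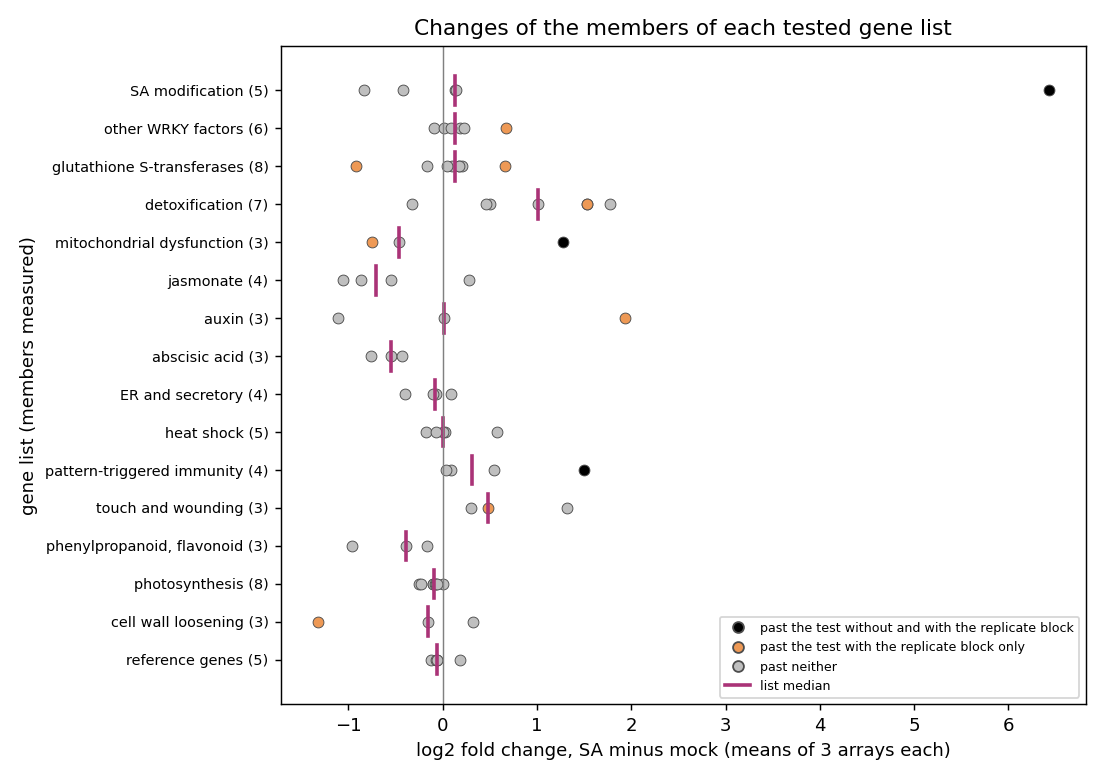
Log2 change between SA and mock (horizontal axis, means of 3 arrays each) of every measured member of the 16 tested gene lists (vertical axis, number of members in brackets). Black points passed the gene test in both fits, orange points with the replicate block only and grey points in neither, and bars give list medians; UGT76B1 stands at 6.43, and the detoxification list has the highest median, 1.01.

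Over all lists, limma called 4 of the 82 measured members, GRX480, UGT76B1, NDB2 and PUB24, and each of them rose. NDB2 and PUB24 passed in none of the fits without 1 array, and GRX480 did not pass without SA replicate 2 (adjusted p = 0.0556), while UGT76B1 passed in all 6. The block added 9 members, so that 10 rises and 3 falls were called. Adjusted over each list alone, which changes no p in a list of 1, there were 10 rises and 3 falls without the block, the falls being GSTU18, AT2G21640 and EXPA8, and 18 rises and 11 falls with it. It changed no list call, and 2 of the 16 lists had an unadjusted camera p under 0.05.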

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

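The weighing of the replicate numbers below used tests chosen after the values were seen.

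The control probe set AFFX-r2-At-U12639_at, which is left out of the comparison, had a log2 signal of 10.29 in SA replicate 2, above the highest mock value of 8.44 in mock replicate 2, while the other 4 arrays lay between 5.45 and 5.65.

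Arrays with the same replicate number deviated together from their group means. A preparation batch that set replicate 1 apart is a candidate explanation: the 3 prime probe set AFFX-DapX-3_at of the dap control, which no plant makes, was 3.11 log2 units higher in replicate 1 than in the mean of replicates 2 and 3, against at most 0.10 between treatments of the same number. Over all 6 dap probe sets the difference ran from 2.23 to 4.00, against at most 0.43. Whether RNA quality or labelling also differed stays open, because the actin probe sets disagree. The signal from the 3 prime end minus that from the 5 prime end was 0.72 higher in replicate 1 by 1 actin pair, against at most 0.15 within a number, and 0.029 higher by the other, against at most 0.20. By the 4 pairs for GAPDH and ubiquitin it was 0.21 to 0.57 higher. A batch that set replicate 1 apart does not account for all of the shared deviations. Without replicate 1, the difference between replicates 2 and 3 still correlated across probe sets between mock and SA by 0.39. The bootstrap lower bound, with genes taken as independent, was 0.36. Whether plants of the same number were also grown or harvested together stays open, and no biological explanation was tested.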

How the results depend on the processing

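Leaving out both arrays numbered 1, the block that sets replicate 1 apart and the block with an estimated correlation were chosen after seeing the data. The 20 genes with the largest changes kept their direction under all alternatives. They were chosen with groups that did not overlap, so leaving out arrays could not reverse them. Blocks and the trended prior leave the log2 change as it is. All 20 stayed past the test with the replicate block, median centring, the dim filter, the trended prior and array weights. All 20 also did with both other probe set rules and the block for replicate 1. With cyclic loess 18 did, with 32 units added 15, without any 1 array between 1 and 11, and without both arrays numbered 1 only 1. The replicate block raised the counts to 1316 genes, 342 genes at 2-fold and 2365 probe sets, and changed no list call. The block for replicate 1 gave 684, 254 and 1262, and array weights 479, 212 and 886 with 0 lists past camera (detoxification adjusted p = 0.0809). Adding 32 linear units gave 135, 63 and 213, and the trended prior 196 probe sets. Testing against a log2 change of 1 kept 1 gene, UGT76B1. Without both arrays numbered 1, 4 genes, all at least 2-fold, and 11 probe sets were called, and 2 of the 4 genes were among the 217. With an estimated correlation 0 lists passed (detoxification adjusted p = 0.882, and 0.763 with the block). Causes were not tested, except that fewer arrays leave fewer degrees of freedom.

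Without mock replicates 1, 2 and 3, 57, 5 and 15 genes were called, and without SA replicates 1, 2 and 3, 22, 6 and 24; the 2-fold count ran from 5 to 55 and probe sets from 0 to 98, lowest without mock replicate 3, SA replicate 2 or SA replicate 3. In the same order, 46, 5, 15, 18, 4 and 24 of those genes were among the 217. The 5 genes without mock replicate 2 were GRX480, UGT76B1, AT3G51350, AT4G02220 and AT4G22530. Lists past camera ran from 0, without mock replicate 1 or 3, to 3 without SA replicate 2; adjusted p ran from 0.000575 to 0.101 for detoxification, from 0.000583 to 0.668 for pattern-triggered immunity and from 0.000849 to 0.710 for touch. Of 301 list values compared, 26 that passed in neither fit differed in direction. Untested lists have no alternatives. Signals near the array floor limit the folds of dim genes.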

Other observations

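The test of neighbouring genes over all calls, and those of gene families and mock replicate 3 in the detoxification list, were chosen after the values were seen; the others in this part were chosen before.

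The block brought in several large changes that were not called without it, named here after their values were seen. AT3G28510 rose by 3.98 log2 units (adjusted p = 0.0504 without the block and 0.00769 with it), and AT4G01870 by 3.24 (0.0702 and 0.00497). AT1G19960 was bright and steady, with 10.40 in mock and 12.52 in SA-treated leaves and pair differences of 1.93, 2.21 and 2.25. SWEET13, a sucrose transporter, fell by 1.73 (0.372 and 0.00626), and AT4G19430, AT3G28270 and AT2G29320 had changes of -2.07, -1.93 and -1.82, with pair differences of AT3G28270 at -1.98, -1.98 and -1.84. A total of 33 families of genes that share a symbol stem had at least 8 members each. Some families share genes, such as EXP and EXPA, so the 33 are not separate sets. After adjustment 0 of the 33 passed camera in either fit. The smallest unadjusted p was 0.0125, for the PRA family of 11 genes (limma camera adjusted p = 0.364), and 2 families lay under 0.05 without the block and 1 with it.

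Called genes lay near called genes of the same direction more often than in shuffled data. Within 5 measured loci, 35 of the 217 genes had such a neighbour, against a mean of 18.0 over 10000 shuffles of the calls along the chromosomes (one-sided permutation p = 0.00330). With the block the excess was smaller in proportion, 597 of 1316 genes against a mean of 523 (permutation p = 0.000500). GRX480 and AT1G28510 rose as adjacent measured loci, AT5G52810 and AT5G52820 likewise, and AT1G78450 and AT1G78460 both fell, with changes of -1.83 and -1.14. Probe sets named as shared between genes are argued against, since all 217 genes were still called when those were left out. The neighbour count was then 39 of 222 genes (permutation p = 0.00150). That repeat is no further test, because no call was removed. Cross-hybridisation between tandem copies within other probe sets stays open, and shared regulation of neighbours may contribute, as an untested hypothesis.

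Of the 7 measured genes of the detoxification list, 5 differed most between SA and mock in the pair numbered 3, and AT2G04050 and AT2G04070 did not. The list medians were 0.66, 0.68 and 1.90 in pairs 1, 2 and 3. The jasmonate list stood apart in the same pair in the other direction, with medians of -0.21, 0.13 and -1.89, but there mock replicate 3 was the highest mock array in THI2.1, PDF1.2 and PDF1.2b, and SA replicate 3 was the lowest SA array in none of them. For the detoxification list, a stronger response of that pair to SA in general is argued against: among 232 genes up at least 2-fold in pair 1, the median change in pair 3 was 1.01 times that in pair 2 (95% bootstrap interval 0.94 to 1.09). A low mock replicate 3 is too, with a list median of -0.052 against the other mock arrays. The SE of the mean over the 7 genes was 0.14. That SE and the bootstrap interval take genes as independent, and neither measures the spread between arrays. Scaling is argued against as well, since the excess was 1.13 after cyclic loess. For that list a local difference in how SA replicate 3 was exposed or handled may remain, as a hypothesis for which no test was available.

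Other splits of the 6 arrays into 3 and 3, of which there are 10 with the real one, are too few for a share under 0.05. As many genes, 2-fold genes or probe sets came from 1 split, the real one: it gave 217, 113 and 334, and the highest other split gave 0, 0 and 0 in limma, with 68 to 1928 genes at an unadjusted p under 0.05. The 3 other splits that part all pairs gave 0 genes with the replicate block as well, against 1316. Every other split keeps the difference between SA and mock inside its groups, which widens their spread. Low counts from those splits are therefore no measure of what chance gives. For gene lists, 6 of the 10 splits gave as many past camera as the real 1, and the highest other split gave 5. That split, mock 1, mock 2 and SA 2 against the rest, holds both arrays numbered 2 on 1 side and both numbered 3 on the other; why lists passed there was not tested. Of the splits that part all pairs the highest other gave 3.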
